A study of Mus musculus with 10 samples.

How the data were processed

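Per the submitters' processing notes, transcripts were quantified with Salmon 0.14.1, and the mm10 and GRCm38.p6 mouse builds are named. Read trimming, the command options and the number of mice are not given in the sources used here. Per the submitters' notes, tumours were digested with collagenase and DNAse, lymphocytes were enriched on Ficoll, CD8 T cells were sorted, RNA was taken with RNeasy Plus Micro columns, and libraries came from a Clontech kit for Illumina sequencing. The labels give the strain as C57BL/6, while the recipients are described as Rag1-deficient B10D2 mice, and this difference is left open.

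Each deposited table gives a transcript's length, effective length, TPM and number of reads, per the file headers. The deposited estimated counts were made by Salmon for each transcript and hold fractions, per the submitters' processing notes, and all tests used them. The deposited TPM values served only as weights in average transcript lengths. The deposited effective lengths, a quantity other than expression, were averaged with those weights for the average transcript length offset alone. Of 140919 transcripts, 139966 were matched to GENCODE M21 and 953 were left out, at most 0.292% of the reads of a library. The release was inferred, because 99.9% of matched transcripts had identical lengths. Estimated reads were summed over the transcripts of 54337 genes and rounded, 102 duplicated symbols were replaced by their gene ID, and 32288 genes had 0 reads everywhere. CPM scale the reads of a gene by the reads on all matched genes of the library, without a TMM factor, and log2 levels used a pseudocount of 1 CPM.

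The libraries ran from 0.0511 M estimated reads (eGFP control 7) to 36.6 M (eGFP control 3), with NFAT5 at 24.9, 18.8 and 22.9, CA-RIT NFAT1 at 29.8, 29.0, 28.3 and 32.5 and eGFP control 6 at 24.8 M. The contrasts, the test, most of the other settings, the 28 gene lists and the rule for naming genes were fixed before the data were examined. After the data were examined, fits with 8 libraries (without eGFP control 7 and CA-RIT NFAT1 10), 7 libraries (also without eGFP control 3) and 6 libraries (NFAT5 and CA-RIT NFAT1 alone, without CA-RIT NFAT1 10) were added, as were the removal of a trend with transcript length and other scalings for 8 libraries.

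Genes were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood fits with TMM scaling, the default low-count filter, a single dispersion trend over the 3 groups and Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.934 over 10 libraries, 0.725 over 8, 0.615 over 7 and 0.485 over 6. Standard errors of log2 fold changes are those implied by the fold change and its test. After TMM scaling the median log2 fold change of all genes over 8 libraries was 0.13, 0.14 and 0.01 in the order NFAT5 against eGFP, CA-RIT NFAT1 against eGFP and CA-RIT NFAT1 against NFAT5. Alternatives were DESeq2 1.42.0 with its defaults, limma 3.58.1 voom with sample quality weights, RLE and upper-quartile scaling, no low-count filter, a filter of 10 reads in 3 libraries with a mean of 5 CPM, only the compared groups, average transcript length offsets, protein-coding genes, counts thinned to the smallest library, and each library left out. Length trends were removed by a lowess offset with span 0.3.

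In a self-test with 200 genes changed by simulation in the comparison of NFAT5 with eGFP, edgeR recovered 0%, 0%, 64.0% and 78.0% of them at an absolute log2 fold change of 1, 2, 4 and 6 over 10 libraries, with 2 false calls. Over 8 libraries it recovered 10.0%, 38.0%, 72.0% and 90.0%, with 6 false calls. With a dispersion of 0.05 it recovered 40.0%, 100.0%, 100.0% and 100.0%.

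Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 84 pairs of list and comparison, with camera at an estimated correlation and fry, for a move in 1 direction and for change in either, beside it. The power of camera at an estimated correlation to find a real shift was not measured. List medians and counts of members on the higher side use the same log2 CPM. The lists were written from general knowledge of the genes: inhibitory receptors, exhaustion transcription factors, stem-like and memory genes, cytotoxic effector genes, cytokines and chemokines, osmotic stress NFAT5 targets, calcineurin-NFAT and anergy genes, T cell activation and AP-1 genes, T cell receptor complex and signalling, tissue residency and homing, cell cycle, interferon response, unfolded protein response, amino acid response and transport, glycolysis and hypoxia, mitochondrial respiratory chain (nuclear), mitochondrial genome, cytosolic ribosomal proteins, cholesterol biosynthesis, heat shock and dissociation stress, apoptosis and survival, mast cell and P511 tumour markers, macrophage and monocyte markers, neutrophil markers, dendritic cell markers, NK and B cell markers, CD4 and regulatory T cell markers, and stromal, endothelial and erythroid markers.

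The rule for naming genes took Nfat5, Nfatc2, Pdcd1, Havcr2, Lag3, Tox, Tcf7, Ifng, Tnf and Gzmb in every comparison, called or not. To these it added, among genes at an adjusted p of 0.05 without overlap between groups, with a mean of at least 5 CPM and a proper symbol, the 10 largest rises and 10 largest falls, and up to 4 called members per list. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were given without a call, and the conditions on symbol and mean CPM were applied to these too. Members named as examples of a list, markers of cell types and genes read for library quality were chosen after values were seen. For a gene with 0 reads in a group, the fold was given against a floor of 3 counts over the group. Exact tests of Nfat5 and Nfatc2 permuted log2(CPM + 1) between the group of that vector and all other libraries, and shares have 95% Wilson intervals. Moderately expressed genes had at least 5 CPM in at least 6 of the 7 libraries other than eGFP control 3, eGFP control 7 and CA-RIT NFAT1 10. Correlations of effects were set against 20 simulations of unchanged groups with the same controls, with a jackknife SE over libraries. No 2 libraries of a group held identical values, and the lowest chi-square per degree of freedom among 12 pairs was 36.4. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, exact tests and figures.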

Results

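CD8 T cells carrying a transgenic receptor for the tumour antigen P1A were activated in culture for 24 h, transduced with a retrovirus and moved into mice bearing P511 mastocytoma, a tumour of mast cell origin. The retrovirus encoded eGFP alone as the control, NFAT5, a transcription factor best known for the response to osmotic stress, or CA-RIT NFAT1, an NFAT1 that is always active and cannot pair with the partner factor AP-1. The CD8 T cells were sorted back from the tumours 7 days after transfer, and their RNA was sequenced. The series concerns the part of NFAT5 in exhaustion, the state of raised inhibitory receptors and reduced function that T cells enter inside tumours. The 10 libraries fell into 3 eGFP control libraries (numbered 3, 6 and 7), 3 NFAT5 libraries (1, 5 and 8) and 4 CA-RIT NFAT1 libraries (2, 4, 9 and 10). Of these, 9 held between 18.8 and 36.6 M estimated reads, and eGFP control 7 held 51112. The labels do not say that the libraries came from separate mice, so p-values measure only the spread between these samples. The tests of genes and of lists, the groups and the gene lists were chosen before the data were examined.

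In 8 of the libraries, transcripts of the transferred T cells were abundant. Cd8a, which encodes the alpha chain of CD8 (chromosome 6, 71373427 to 71379173), lay between 582 and 988 CPM (reads scaled to the reads on all matched genes) in them. Reads on T cell receptor beta variable segments fell on Trbv5 in at least 99.9% of cases, and reads on alpha variable segments fell on Trav12-3 in 98.1% to 98.4%. CA-RIT NFAT1 10 was different in kind, with 1 read on Cd8a (0.0308 CPM) among 32.5 M. Trbc2, a constant segment of the receptor beta chain, was at 41.2 CPM there against 15593 to 25613 CPM in the 8 libraries. Of its 177 reads on alpha variable segments, 62 fell on Trav12-3, a share of 35.0% (95% Wilson interval 28.4% to 42.3%). Its few reads on beta variable segments went the other way, with 248 of 258 on Trbv5 (96.1%, 93.0% to 97.9%). In the same library Cpa3, the mast cell carboxypeptidase (chromosome 3, 20215620 to 20242181), reached 1859 CPM, and Kit, the stem cell factor receptor of mast cells (chromosome 5, 75574916 to 75656722), reached 505 CPM. Trap1a, the gene of the P1A antigen (chromosome X, 139333683 to 139338169), reached 331 CPM there, and the macrophage gene Chil3 reached 2997 CPM. Across the 8 libraries these 4 genes peaked at 66.1, 33.7, 24.9 and 73.9 CPM.

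eGFP control 7 gave reads on 798 genes, and its 10 highest genes, led by the class I histocompatibility gene H2-D1, took 60.8% of its reads (95% Wilson interval 60.4% to 61.2%). When eGFP control 6 was thinned at random to the same 51104 reads it still showed 7354 genes, with 9.75% of reads on its 10 highest. Cd8a had 0 reads in eGFP control 7, where 3 counts equal 58.7 CPM. Another pattern was seen in eGFP control 3, the deepest library. Of 8634 genes expressed at moderate levels, 356 (4.12%) had 0 reads in it, among 854 (9.89%) in CA-RIT NFAT1 10, 7924 (91.8%) in eGFP control 7 and at most 1 in each of the others. The median correlation of log2 CPM with the 7 remaining libraries was 0.837 for eGFP control 3, 0.625 for CA-RIT NFAT1 10 and 0.234 for eGFP control 7, against 0.953 to 0.963 among those 7. All 10 libraries entered the comparisons as planned. Each was then repeated with 8 libraries, leaving out eGFP control 7 and CA-RIT NFAT1 10, a choice made after seeing the data. Intervals and floors given here cover counting error only.

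**Figure D1:**
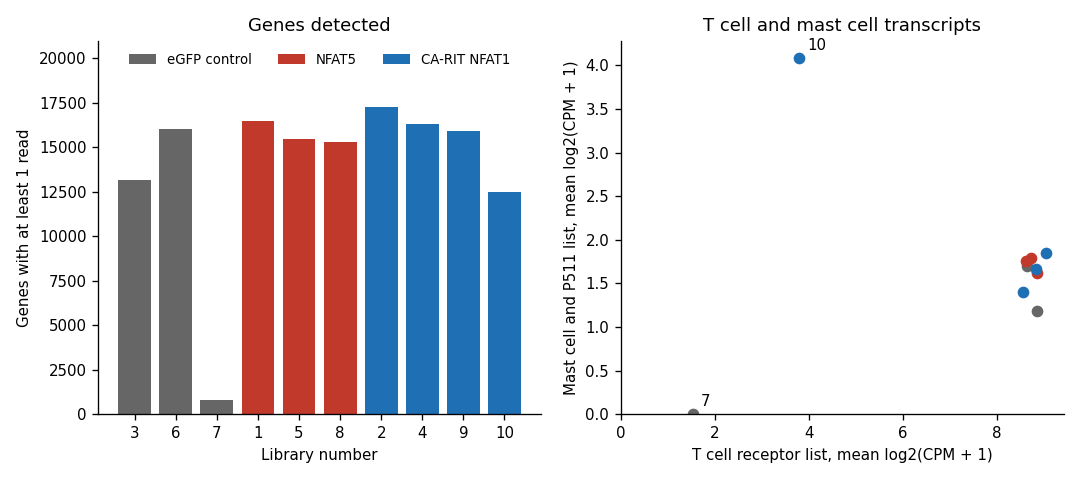
Left, bars give the number of genes with at least 1 read in each library, by group, from 798 in eGFP control 7 to 17255 in CA-RIT NFAT1 2. Right, each point is a library placed by the mean log2(CPM + 1) of the T cell receptor list and of the mast cell and P511 list, with CA-RIT NFAT1 10 at 3.80 and 4.08 and eGFP control 7 near the lower left.

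Nfat5 itself (ENSMUSG00000003847, chromosome 8, 107293470 to 107379517, plus strand) marked the NFAT5 libraries. Its level over 8 libraries was 72.2 ± 21.1 CPM with NFAT5 (SD, n = 3), 4.00 ± 4.07 CPM with eGFP (n = 2) and 6.15 ± 4.06 CPM with CA-RIT NFAT1 (n = 3), and it was 0.0923 CPM in CA-RIT NFAT1 10. eGFP control 7 had 0 reads of it, which cannot place that library, since 3 counts there exceed the 48.0 CPM of the lowest NFAT5 library. An exact test over 10 libraries is void for this reason. Among the 8 libraries the lowest with NFAT5 lay above the highest of the others, at 10.7 CPM, and an exact two-sided permutation test of log2(CPM + 1) gave p = 0.0357, the smallest its 56 splits allow. Most of these reads were assigned to Nfat5-211, a coding transcript of 4982 bases with 9 bases of annotated 3' untranslated region. It took 87.0% of Nfat5 reads in NFAT5 1 (95% Wilson interval 85.5% to 88.4%), 84.1% in NFAT5 5 (82.1% to 85.8%) and 71.8% in NFAT5 8 (69.0% to 74.3%). In CA-RIT NFAT1 2 it took 33 of 319 reads (10.3%, 7.46% to 14.2%), and it had 0 reads in the remaining libraries. Nfatc2, the gene of NFAT1 (ENSMUSG00000027544, chromosome 2, 168476410 to 168601657, minus strand), did not separate the CA-RIT NFAT1 libraries. It lay at 60.7 ± 29.5 CPM with CA-RIT NFAT1 (SD, n = 3), 49.6 ± 17.9 CPM with NFAT5 (n = 3) and 25.7 ± 30.7 CPM with eGFP (n = 2), with exact two-sided permutation p = 0.429 over the 8 libraries, and at 3.39 CPM in CA-RIT NFAT1 10. Of its transcripts, Nfatc2-201, picked after values were seen, took 9.48% and 13.4% of Nfatc2 reads in CA-RIT NFAT1 2 and 4, and 11.2% of few reads in CA-RIT NFAT1 10. In CA-RIT NFAT1 9 it took 4.21%, within the 0% to 4.64% of the NFAT5 libraries and eGFP control 3 and 6. The labels of the CA-RIT NFAT1 libraries are therefore not checked by a vector transcript.

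**Figure D2:**
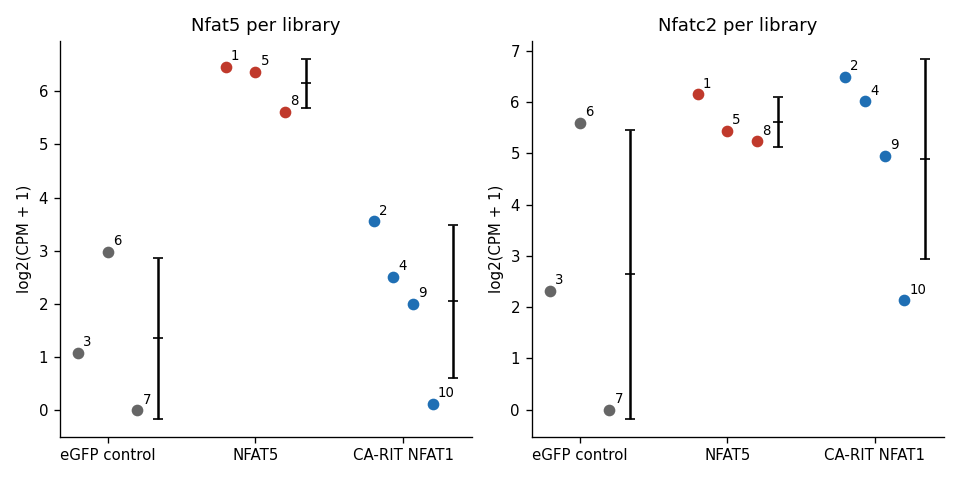
Each point is the log2(CPM + 1) of Nfat5 (left) or Nfatc2 (right) in a library, numbered and grouped by vector, and the bars give the group mean and SD. The 3 NFAT5 libraries lie above the others for Nfat5, apart from eGFP control 7, whose 0 reads at low depth cannot place it, while the groups overlap for Nfatc2.

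The first comparison, NFAT5 against eGFP, asks what extra NFAT5 changed in the transcriptome of tumour-infiltrating T cells. Inhibitory receptor genes, which restrain T cells, were lower with NFAT5 as a group, as were cytotoxic effector genes and the genes of cytokines and chemokines, while cell cycle genes were higher. Those 4 directions, each relative to the other genes tested, were called by camera both over 10 libraries and over 8. With an estimated correlation none of them was, with adjusted p = 0.992 for each over 10 libraries and adjusted p = 0.931 for each over 8. In the 8 libraries 0 of 19 inhibitory receptor genes had a higher level with NFAT5, and their median log2 fold change was -0.92 (adjusted p = 1.36e-05, and adjusted p = 0.931 with an estimated correlation). Havcr2, which encodes TIM-3, averaged 134 ± 57.7 CPM with NFAT5 (SD, n = 3) and 279 ± 25.5 CPM with eGFP (n = 2), a log2 fold change of -1.17 ± 0.34 (SE). Cd160 had -1.26 ± 0.34 and Entpd1, the ectonucleotidase CD39, had -0.90 ± 0.36. Pdcd1, which encodes PD-1, had -0.76 ± 0.63, Lag3 -0.59 ± 0.81 and the exhaustion factor Tox -0.15 ± 0.54. Cd160 had -0.65 without eGFP control 3, and with 1 library left out Pdcd1 ran from -1.70 to -0.39, Lag3 from -1.45 to 0.70 and Tox from -0.63 to 0.34. None of these genes passed on its own, 4 of the 19 had an unadjusted p below 0.05, and 0 passed when adjusted over the list alone.

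Among cytotoxic effector genes, 4 of 21 were on the higher side with NFAT5 over 8 libraries (median -0.52, adjusted p = 6.36e-04, and adjusted p = 0.931 with an estimated correlation). Gzmb, the gene of granzyme B, averaged 2322 ± 796 CPM against 8121 ± 4737 CPM (log2 fold change -1.95 ± 0.43), and it was the 1 member past the threshold when adjusted over the list alone. Prf1, the gene of perforin, had -1.69 ± 0.60 and Nkg7 -1.02 ± 0.32. Gzmf had 0 reads in the controls, and with it at a floor of 3 counts the median log2 ratio of group means in CPM was -0.45. Of 20 cytokine and chemokine genes 5 were on the higher side (median -0.73, adjusted p = 0.0358, and adjusted p = 0.931 with an estimated correlation), and 5 passed when adjusted over the list alone. These were Ccl3 at -3.16 ± 0.65, Ccl4 at -2.94 ± 0.54, Csf2 at -2.62 ± 0.81 and Il10 at -1.96 ± 0.57, with Tnf going the other way at 2.68 ± 0.78. Tnf lay at 124 ± 55.8 CPM with NFAT5 and 18.0 ± 3.72 CPM with eGFP, and Ifng, at -0.96 ± 0.35, lay at 334 ± 70.6 and 597 ± 302 CPM. Cell cycle genes were higher in 36 of 40 cases (median 0.63, adjusted p = 2.24e-04, and adjusted p = 0.931 with an estimated correlation), as in Mki67 at 1.09 ± 0.27, Kif11 at 1.42 ± 0.39 and Top2a at 1.22 ± 0.38, with 0 passing when adjusted over the list alone. Without eGFP control 3 the values were -1.07 for Gzmb, -0.32 for Nkg7, -1.75 for Ccl3, -1.40 for Ccl4, -0.22 for Ifng, 0.93 for Kif11 and 0.70 for Top2a, and without eGFP control 6 Kif11 had 2.23 and Top2a 2.08.

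A pair of metabolic lists was also lower over 8 libraries. For glycolysis and hypoxia genes, 7 of 34 were on the higher side (median -0.42, adjusted p = 3.01e-04, and adjusted p = 0.931 with an estimated correlation). Among the others were Bnip3 at -2.15 ± 0.66, Tpi1 at -1.12 ± 0.38 and Aldoa at -0.91 ± 0.28. P4ha2 had 0 reads in both groups, and with floors of 3 counts the median log2 ratio of group means in CPM was -0.30. For nuclear genes of the respiratory chain, 7 of 51 were on the higher side (median -0.27, adjusted p = 0.00173, and adjusted p = 0.947 with an estimated correlation). Uqcrh was among the others at -0.89 ± 0.34, and 0 members of either list passed when adjusted over the list alone. Bnip3 had -1.01, Tpi1 -0.46 and Uqcrh -0.13 without eGFP control 3, and without eGFP control 6 Uqcrh had -1.38. The osmotic stress targets of NFAT5 showed no call (median -0.26, adjusted p = 0.179), and neither did exhaustion transcription factors (median 0.19, adjusted p = 0.996) or stem-like and memory genes (median 0.23, adjusted p = 0.969). Tcf7, the TCF-1 gene of the memory list, was at 0.219 CPM in eGFP control 3, 74.7 CPM in eGFP control 6 and 103 ± 48.7 CPM with NFAT5, a log2 fold change of 1.40 ± 1.42 that ran from 0.42 without eGFP control 3 to 8.67 without eGFP control 6. Markers of other cells went both ways. Lyz2, a macrophage gene, had 0 reads in eGFP control 3 and 6 and 32.0 ± 30.7 CPM with NFAT5, at least 653-fold higher against 3 counts over the control group, or at least 263-fold without eGFP control 3. Cd74 and H2-Ab1, genes of antigen presentation, were at 565 and 454 CPM in eGFP control 3. The lists of macrophage (median -0.51, 9 of 27 higher, adjusted p = 0.462), neutrophil (0.94, 7 of 10, 0.308), dendritic cell (-1.15, 4 of 12, 0.176) and mast cell and P511 markers (0.96, 11 of 14, 0.308) were not called, although 3, 3, 1 and 0 of their members passed when adjusted over the list alone.

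Of single genes, none of 13783 passed an adjusted p of 0.05 in edgeR over 10 libraries, where 374 had an unadjusted p below 0.05, DESeq2 called 0 higher and 10 lower, and limma voom called 1, H2-D1, as lower. Over 8 libraries edgeR called none of 14473 genes, with 1051 at an unadjusted p below 0.05. DESeq2 called 75 higher and 29 lower, and voom called none. Nfat5 had a log2 fold change of 4.14 ± 1.45 (adjusted p = 1, edgeR) over 10 libraries and 4.11 ± 0.89 (adjusted p = 0.654) over 8. Nfatc2 had 0.96 ± 1.13 over 10 libraries, from 0.18 without eGFP control 3 to 3.47 without eGFP control 6, and 0.89 ± 0.85 over 8, from 0.04 to 3.46. The 5 genes with the smallest p in each direction over 8 libraries included, besides Nfat5 and Lyz2, Dusp5 at 1.57 ± 0.35, Jade3 at 2.60 ± 0.59 and Vps37b at 1.08 ± 0.22. With the values given above for Ccl3 and Ccl4, which are -1.75 and -1.40 without eGFP control 3, the lower side held Miga1, a gene of mitochondrial fusion, at -2.24 ± 0.28, Tnfsf4, which encodes OX40 ligand, at -1.72 ± 0.33, and Gem at -1.60 ± 0.32. Miga1 had the smallest adjusted p, 0.285. Over 10 libraries the 5 higher were Tgif1 at 1.90 ± 0.49, Zfp36l2 at 2.35 ± 0.69, Pou2f1 at 2.65 ± 0.77, Lyz2 at 10.18 ± 2.89 and Gpt2. For Lyz2 the fitted value rests on a single read in the controls, in eGFP control 7, where it equals 19.6 CPM and lies within the 12.6 to 67.4 CPM of the NFAT5 libraries, and the group means were 32.0 and 6.52 CPM. Gpt2 had 0 reads in all 3 controls and was at least 69.3-fold higher against 3 counts over the group, or at least 28.0-fold without eGFP control 3. The 5 lower were Cyp4f13 at -3.35 ± 0.89, Malat1 at -2.80 ± 0.75, Lonrf1 at -12.98 ± 3.48, Shank1 at -12.29 ± 3.42 and Nphs1 at -12.16 ± 3.57, with Shank1 at 685 CPM and Nphs1 at 1135 CPM in eGFP control 7 and at most 0.741 and 0.693 CPM elsewhere. Without eGFP control 7 Lonrf1 had -6.46, Shank1 -0.95 and Nphs1 0.84, and without eGFP control 3 Cyp4f13 had -1.42 and Malat1 -0.75. Of 8700 genes with a mean of at least 5 CPM, 2089 (24.0%) had libraries that did not overlap between the groups over 8 libraries, where chance gives 20%.

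The calls on lists rested on few controls. Without eGFP control 3, which left eGFP control 6 alone and assumed to vary like the other groups, the cytotoxic (-0.32, adjusted p = 0.0778) and cytokine lists (-0.25, 0.396) lost their calls, the cell cycle median was 0.34 and the respiratory chain turned to 0.17 (0.137). Without eGFP control 6 the cytokine list had -1.07 (0.079) and the respiratory chain -0.70, the cytokine list had -0.42 without NFAT5 5 and -0.43 (0.0758) without NFAT5 8, the respiratory chain had -0.05 (0.335) without NFAT5 1 and -0.41 without NFAT5 8, and the stricter filter ended the cytokine call (-0.52, 0.119). With a trend with transcript length removed the cytokine and respiratory chain lists were not called (0.0673 and 0.06), although their medians moved little. These were -0.73 (quartiles of members -1.59 and 0.09) before and -0.78 (-1.73 and -0.02) after for cytokines, and -0.27 (-0.46 and -0.09) before and -0.22 (-0.40 and -0.05) after for the respiratory chain. The mean of the genes they are set against fell from 0.36 to 0.13 in the same step, which narrowed the gap, and cell cycle had 0.34 and glycolysis -0.64.

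**Figure D3:**
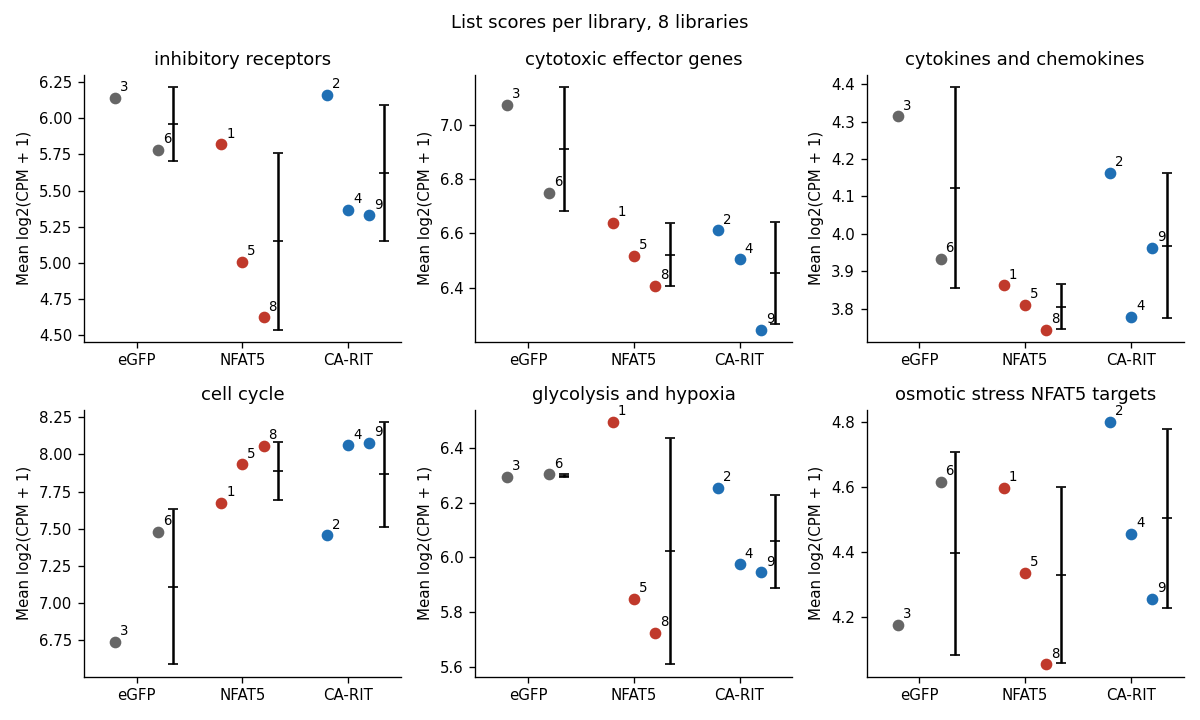
Each point is the mean log2(CPM + 1) of a gene list in a library, numbered, for 6 lists over the 8 libraries, with bars for the group mean and SD. For inhibitory receptors NFAT5 1, at 5.82, lies between the controls at 5.78 and 6.14, while NFAT5 5 and 8 lie at 5.01 and 4.62.

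The second comparison, CA-RIT NFAT1 against eGFP, asks what an NFAT1 that cannot work with AP-1 changed in the same cells. Cytotoxic effector and inhibitory receptor genes were lower as groups and cell cycle genes higher, relative to the other genes, in directions called by camera both over 10 libraries and over 8. With an estimated correlation none of the 3 was called, with adjusted p = 0.992 for each over 10 libraries and, over 8, adjusted p = 0.931 for the first pair and adjusted p = 0.947 for cell cycle. Over 10 libraries the medians of the lists called lower were again positive and below the median of all genes. Over the 8 libraries, 5 of 21 cytotoxic genes were on the higher side (median -0.52, adjusted p = 3.01e-04, and adjusted p = 0.931 with an estimated correlation). Gzmb averaged 2774 ± 720 CPM (SD, n = 3) against 8121 ± 4737 CPM (n = 2), a log2 fold change of -1.71 ± 0.42, with Gzma at -1.73 ± 0.61 and Nkg7 at -0.98 ± 0.32. With Gzmf at its floor the median log2 ratio of group means in CPM was -0.37. Of the inhibitory receptors 3 of 19 were on the higher side (median -0.45, adjusted p = 0.00928, and adjusted p = 0.931 with an estimated correlation), and the others included Klrc1 at -0.43 ± 0.22, Lilrb4a at -1.32 ± 0.71 and Klrd1 at -0.98 ± 0.55. Pdcd1 had -0.30 ± 0.64, Havcr2 -0.44 ± 0.34, Lag3 0.23 ± 0.82 and Tox 0.28 ± 0.55. With 1 library left out Klrc1 had -0.28 and Klrd1 -0.60 (without CA-RIT NFAT1 9), Klrd1 ran to -1.66, Pdcd1 from -0.56 to 0.01, Havcr2 from -0.62 to -0.28, Lag3 from -0.58 to 1.51 and Tox from -0.29 to 0.76. Without eGFP control 3 Gzmb had -0.83, Gzma -1.15, Nkg7 -0.29 and Lilrb4a 0.59, and without eGFP control 6 Lilrb4a had -2.11. Cell cycle genes were higher in 34 of 40 cases (median 0.62, adjusted p = 9.45e-04, and adjusted p = 0.947 with an estimated correlation), with Mki67 at 1.27 ± 0.27, Kif11 at 1.26 ± 0.39, from 0.77 to 2.07 with 1 library left out, and Cenpe at 1.19 ± 0.33. In these 3 lists 0 members passed when adjusted over the list alone.

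The metabolic and ribosomal lists were lower over 8 libraries. Glycolysis and hypoxia genes were on the higher side in 7 of 34 cases (median -0.42, adjusted p = 3.04e-04, and adjusted p = 0.931 with an estimated correlation), and the others included Bnip3 at -2.53 ± 0.66, Higd1a at -1.24 ± 0.42 and Tpi1 at -1.11 ± 0.38. With P4ha2 at its floor in the controls the median log2 ratio of group means in CPM was -0.32. Nuclear respiratory chain genes were on the higher side in 4 of 51 cases (median -0.42, adjusted p = 3.59e-06, and adjusted p = 0.931 with an estimated correlation), and the others included Uqcrh at -1.01 ± 0.34 and Ndufa7 at -0.86 ± 0.34. Of 48 genes of cytosolic ribosomal proteins 0 were on the higher side (median -0.30, adjusted p = 3.29e-05, and adjusted p = 0.947 with an estimated correlation), with Rps27 at -0.55 ± 0.26 and Rpl19 at -0.57 ± 0.27. Without eGFP control 3 these genes had -1.39 (Bnip3), -0.16 (Higd1a), -0.46 (Tpi1), -0.25 (Uqcrh), -0.11 (Ndufa7), -0.32 (Rps27) and -0.07 (Rpl19), and without eGFP control 6 Ndufa7 had -1.34 and Rpl19 -0.93. In these lists too, 0 members passed when adjusted over the list alone. Cytokine and chemokine genes were not called (adjusted p = 0.179), although 2 members passed when adjusted over the list alone. Ifng had -0.93 ± 0.35, Tnf 1.75 ± 0.75 and Tcf7 1.74 ± 1.45, and with 1 library left out they ran from -1.40 to -0.19, from 0.71 to 2.14 and from 0.76 to 9.01. Calcineurin-NFAT and anergy genes, targets of NFAT1, were not called either (adjusted p = 0.547), nor were exhaustion transcription factors (0.718), where 2 members passed when adjusted over the list alone. Lyz2 was at 26.1 ± 23.9 CPM with CA-RIT NFAT1, at least 533-fold higher than 3 counts over the controls, or at least 215-fold without eGFP control 3, and of the lists of other cells, the macrophage (median 0.29, 16 of 27 higher, adjusted p = 0.812), neutrophil (1.78, 7 of 10, 0.318) and dendritic cell lists (-0.48, 4 of 12, 0.969) were not called, with 5, 2 and 2 members past the threshold when adjusted over the list alone.

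Over 10 libraries edgeR called none of the 13783 genes, with 609 at an unadjusted p below 0.05, DESeq2 called 1 higher and 12 lower, and voom called 2, both lower. Over 8 libraries edgeR called none of 14473, with 932 at an unadjusted p below 0.05, DESeq2 called 44 higher and 16 lower, and voom called none. Nfatc2 had a log2 fold change of 0.84 ± 1.08 over 10 libraries and 1.16 ± 0.86 over 8, and Nfat5 had 0.14 ± 1.17 and 0.53 ± 0.75. Nfatc2, with 1 library left out, ran from 0.06 to 3.35 and from 0.31 to 3.74, and Nfat5 from -0.64 to 1.83 and from -0.22 to 2.26. Over 8 libraries the 5 higher genes with the smallest p were Lyz2, Mki67, Nr4a3 at 2.14 ± 0.41, Pou2f1 at 3.03 ± 0.63 and Mast2 at 2.07 ± 0.47. The 5 lower were Miga1 at -2.56 ± 0.28, with the smallest adjusted p of 0.181, Ccl4 at -2.44 ± 0.53, Pnrc2 at -0.97 ± 0.21, Gem at -1.38 ± 0.32 and H2-Ab1 at -2.54 ± 0.57. Ccl4 had -0.90 and H2-Ab1 -0.82 without eGFP control 3. Over 10 libraries the higher genes were Mast2 at 2.37 ± 0.54, Pou2f1 at 3.39 ± 0.79, Arhgap21 at 3.64 ± 0.94, Gpt2, at least 469-fold higher, and Fam198b, at least 585-fold higher, both with 0 reads in the controls. Without CA-RIT NFAT1 10, where both are highest, the limits are 104-fold and 84.8-fold, and without eGFP control 6 Arhgap21 had 5.65. The lower genes were Rps12 at -7.53 ± 1.88, Snx22 at -8.74 ± 2.22, Nphs1 at -12.66 ± 3.17, Shank1 at -11.16 ± 2.86 and Fgf9 at -15.75 ± 4.09. All 5 rest on eGFP control 7, without which they had -0.42, -0.07, 0.33, 0.16 and 1.47 in that order. Non-overlapping genes numbered 1895 of 8700 (21.8%, where chance gives 20%) over 8 libraries. Without eGFP control 3 the inhibitory receptor call was lost (-0.34, adjusted p = 0.6), as were those of the respiratory chain (-0.01, 0.929) and ribosomal proteins (0.02, 0.99), the cytotoxic median was -0.29 and the cell cycle median 0.35. Without CA-RIT NFAT1 9 the calls of inhibitory receptors (-0.41, adjusted p = 0.0596) and cell cycle (0.42, 0.0596) were lost, with -0.32 for cytotoxic and -0.47 for ribosomal genes, the respiratory chain and ribosomal medians were -0.89 and -0.58 without eGFP control 6 and -0.27 and -0.13 without CA-RIT NFAT1 2. Removing a trend with transcript length ended the cell cycle call, with the median going from 0.62 (quartiles 0.13 and 1.15) to 0.23 (-0.04 and 0.52, adjusted p = 0.058), and the ribosomal call, from -0.30 (-0.39 and -0.18) to -0.11 (-0.25 and 0.00, 0.288). The same step gave -0.83 for inhibitory receptors, -0.65 for glycolysis and -0.28 for the respiratory chain.

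Leaving out eGFP control 6 moved the gene counts of both comparisons far more than any other change, while over 10 libraries leaving out eGFP control 3 or 7 left them at 0. Without eGFP control 6, which left eGFP control 3 as the control with deep reads, edgeR called 496 genes higher and 10 lower with NFAT5 and 602 higher and 37 lower with CA-RIT NFAT1 among the remaining 9 libraries. From the 8 libraries, the same step left eGFP control 3 as the only control, with no spread between controls. In that library 4.12% of moderately expressed genes had 0 reads. The gene counts of that fit are therefore not given.

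The last comparison, CA-RIT NFAT1 against NFAT5, tests whether the effects of the vectors differ. Over 8 libraries inhibitory receptor genes were higher with CA-RIT NFAT1 than with NFAT5 in 17 of 19 cases (median 0.59, adjusted p = 0.0012, and adjusted p = 0.931 with an estimated correlation). Cd160 had a log2 fold change of 0.75 ± 0.31, Havcr2 0.73 ± 0.31 and Tigit 0.68 ± 0.31, with Pdcd1 at 0.46 ± 0.57, Lag3 at 0.82 ± 0.74 and Tox at 0.43 ± 0.49. Without NFAT5 1 Havcr2 had 1.12, without CA-RIT NFAT1 2 Tigit had 0.44, and with 1 library left out Pdcd1 ran from 0.11 to 1.42, Lag3 from -0.01 to 1.71 and Tox from -0.16 to 0.94. Over 10 libraries that list was not called (median -1.21, adjusted p = 0.484). Dendritic cell markers were higher over 10 libraries and over 8, in 8 of 12 cases over the latter (median 0.75, adjusted p = 3.34e-04, and adjusted p = 0.931 with an estimated correlation). Wdfy4, the 1 member past the threshold when adjusted over the list alone, had 0 reads with NFAT5, and with it at its floor the median log2 ratio of group means in CPM was 0.72, while Zbtb46 had 2.51 ± 1.02 and Batf3 2.26 ± 0.98. Ribosomal protein genes were lower as a group, with 3 of 48 on the higher side (median -0.18, adjusted p = 3.24e-04, and adjusted p = 0.947 with an estimated correlation). Rps27, among the others, had -0.44 ± 0.23. Respiratory chain genes were also lower, with 3 of 51 on the higher side (median -0.15, adjusted p = 0.00752, and adjusted p = 0.972 with an estimated correlation). Ndufa4, among the others, had -0.39 ± 0.32, from -0.61 to -0.21 with 1 library left out. In the inhibitory receptor, ribosomal and respiratory chain lists 0 members passed when adjusted over the list alone. Tcf7 had 0.34 ± 1.21, Ifng 0.03 ± 0.32, Tnf -0.93 ± 0.63 and Gzmb 0.24 ± 0.38, and with 1 library left out they ran from 0.06 to 0.74, from -0.13 to 0.16, from -1.97 to -0.55 and from 0.05 to 0.54.

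Over 10 libraries macrophage and monocyte markers were higher with CA-RIT NFAT1 than with NFAT5 (median 1.61, adjusted p = 4.75e-11), and so were mast cell and P511 markers (0.85, 0.00357) and dendritic cell markers (0.53, 0.0168). Interferon response genes (-1.57, 2.34e-05), T cell receptor genes (-1.79, 1.7e-04), cytotoxic genes (-1.12, 0.00143) and residency and homing genes (-0.89, 0.035) were lower, and each of these 7 lists had an adjusted p of 0.992 with an estimated correlation. In CA-RIT NFAT1 10 the T cell receptor list score was 3.80 and the mast cell and P511 score 4.08, against 8.57 to 9.05 and 1.40 to 1.85 in the other CA-RIT NFAT1 libraries. Over the 8 libraries the macrophage (adjusted p = 0.4), mast cell (0.471), interferon (0.771), T cell receptor (0.547), cytotoxic (0.969) and residency lists (0.898) were not called.

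Of single genes edgeR called none over 10 libraries, with 181 at an unadjusted p below 0.05, DESeq2 called 1 higher, Apc2, and voom called none. Apc2, named here after its values were seen, was at 58.3 CPM in CA-RIT NFAT1 10 and at most 5.02 CPM elsewhere. Over 8 libraries edgeR called none, with 163 at an unadjusted p below 0.05, DESeq2 called 1 lower, Nfat5 (adjusted p = 8.46e-04), and voom called none, with Nfat5 at adjusted p = 0.051. In edgeR Nfat5 had -3.99 ± 1.10 (adjusted p = 1.00) over 10 libraries and -3.58 ± 0.72 (adjusted p = 1.00) over 8, and Nfatc2 had -0.12 ± 0.94 (from -0.60 to 0.28 with 1 library left out) and 0.27 ± 0.74 (from -0.07 to 0.60). The 5 higher genes with the smallest p over 8 libraries were Tnfsf4 at 1.32 ± 0.31, Cd80 at 1.27 ± 0.33, Serpinb9b at 0.92 ± 0.24, Ptpn6, the gene of the phosphatase SHP-1, at 0.73 ± 0.20, and Wdr91 at 1.54 ± 0.46. The lower ones besides Nfat5 were Plac8 at -0.80 ± 0.20, Hist1h2ao at -0.89 ± 0.30, Vps37b at -0.46 ± 0.19 and Socs1 at -0.73 ± 0.32. Over 10 libraries the higher genes were Arhgap21 at 2.38 ± 0.75, Inpp4b at 1.95 ± 0.63, Wdr91 at 1.60 ± 0.53, Plbd1 at 6.32 ± 2.25 and Nhlrc1, with 0 reads in the NFAT5 libraries and at least 307-fold higher. Nhlrc1 and Plbd1 rest on CA-RIT NFAT1 10, without which the limit is 15.1-fold and the log2 fold change 2.08, and without NFAT5 8 Plbd1 had 9.05. The lower ones were Nfat5, Hist1h2ao at -1.13 ± 0.44, Plac8 at -1.01 ± 0.44, Hemk1 at -1.61 ± 0.74 and Ccnl1 at -0.75 ± 0.40. Non-overlapping genes numbered 487 of 8700 (5.60%, where chance gives 10%) over 8 libraries and 233 of 8854 (2.63%, where chance gives 5.71%) over 10. The inhibitory receptor call was lost without CA-RIT NFAT1 2 (0.26, adjusted p = 0.285) and without NFAT5 8 (0.14, 0.319) and had 0.33 without NFAT5 5, and the dendritic cell median turned to -0.05 (0.543) with a mean CPM of at least 5 and was 0.42 without NFAT5 5. The calls of cytosolic ribosomal proteins and the respiratory chain were lost without CA-RIT NFAT1 2 (-0.04, 0.623 and -0.02, 0.931), without NFAT5 8 (-0.09, 0.396 and -0.03, 0.815) and with the length trend removed (-0.06, 0.354 and -0.05, 0.392), the respiratory chain also without NFAT5 5 (-0.11, 0.18), and they had -0.32 and -0.32 without NFAT5 1 and -0.38 and -0.27 without CA-RIT NFAT1 9. Quartiles of the members went from -0.26 and -0.11 to -0.11 and 0.00 (ribosomal) and from -0.21 and -0.10 to -0.10 and 0.00 (respiratory chain) when the length trend was removed.

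In the planned tests over 10 libraries, 23 of the 84 pairs of list and comparison passed, and 7 passed without CA-RIT NFAT1 10. The median log2 fold change of all genes was 2.69 for NFAT5 and 2.54 for CA-RIT NFAT1 against eGFP in that fit, which holds eGFP control 7, so the lists called lower in it have positive medians. With NFAT5 these were dendritic cell markers (0.75, adjusted p = 0.00187), cytotoxic genes (2.47, 0.00736), genes of the mitochondrial genome (2.50, 0.0179), inhibitory receptors (2.10, 0.0194), macrophage markers (2.11, 0.0242) and cytokines (1.33, 0.0414), with cell cycle genes higher (4.20, 0.00935). With CA-RIT NFAT1 (3 members of the mitochondrial genome past the threshold when adjusted over the list alone) the lower ones were cytotoxic genes (0.33, 4.26e-07), T cell receptor genes (1.47, 0.00187), inhibitory receptors (0.88, 0.00661), the mitochondrial genome (2.20, 0.00935), residency and homing (1.17, 0.0168), interferon response (1.65, 0.0241) and cytokines (1.32, 0.0272), with cell cycle (3.95, 0.0179) and mast cell and P511 markers (4.18, 0.0278) higher. None of the 23 held with an estimated correlation (lowest adjusted p = 0.992). Over 8 libraries 16 pairs passed, of which 8 had been called in the same direction over 10, and again none held with an estimated correlation (lowest adjusted p = 0.931). Fry, which asks whether a list changes at all and does not set it against other genes, passed no list for a move in 1 direction (lowest adjusted p of the 84 pairs 0.691 over 10 libraries and 0.28 over 8). For change in either direction it passed none over 10 libraries and 3 pairs of list and comparison over 8, all with lists named for other cells. These were dendritic cell markers with CA-RIT NFAT1 against eGFP (adjusted p = 9.57e-05, at most 0.0053 with 1 library left out) and against NFAT5 (1.5e-05, at most 5.72e-04), and neutrophil markers with NFAT5 against eGFP (0.00334, but 0.977 without eGFP control 3, 0.606 without NFAT5 8 and 0.0842 without CA-RIT NFAT1 4). The dendritic cell list shares Bst2, Ccr7 and Batf3 with the interferon, stem-like and activation lists, so a change in it need not reflect other cells. With CA-RIT NFAT1 against NFAT5, however, the 3 members with the smallest p were Wdfy4, Zbtb46 and Batf3, of which only Batf3 is shared. Wdfy4 had 0 reads with NFAT5, and which cells gave these reads was not tested.

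The lists that passed in no comparison over 8 libraries had the following adjusted p-values in the order NFAT5 against eGFP, CA-RIT NFAT1 against eGFP and CA-RIT NFAT1 against NFAT5. Osmotic stress targets had 0.179, 0.471 and 0.462, and calcineurin-NFAT and anergy genes 0.969, 0.547 and 0.179. Exhaustion transcription factors had 0.996, 0.718 and 0.416, stem-like and memory genes 0.969, 0.539 and 0.179, and activation and AP-1 genes 0.416, 0.539 and 0.643. T cell receptor genes had 0.0775, 0.176 and 0.547, residency and homing genes 0.969, 0.969 and 0.898, and interferon response genes 0.547, 0.465 and 0.771. With the length trend removed, camera called T cell receptor genes lower with NFAT5 against eGFP (median -0.24, adjusted p = 0.0285). That call was not tested with an estimated correlation. The unfolded protein response had 0.179, 0.268 and 0.812, amino acid response genes 0.641, 0.474 and 0.891, cholesterol biosynthesis 0.462, 0.513 and 0.89, heat shock genes 0.326, 0.164 and 0.498, and apoptosis genes 0.474, 0.312 and 0.641. The mitochondrial genome had 0.969, 0.525 and 0.179. Of the other markers, macrophage had 0.462, 0.812 and 0.4, neutrophil 0.308, 0.318 and 0.969, mast cell and P511 0.308, 0.521 and 0.471, NK and B cell 0.969, 0.969 and 0.996, CD4 and regulatory T cell 0.179, 0.718 and 0.0781, and stromal 0.969, 0.771 and 0.718. The remaining pairs not called were ribosomal proteins with NFAT5 (0.0775), dendritic cell markers with NFAT5 (0.176) and CA-RIT NFAT1 (0.969) against eGFP, cytokines with CA-RIT NFAT1 against eGFP (0.179) and in the last comparison (0.179), and there also cell cycle (0.471), glycolysis (0.969) and cytotoxic genes (0.969). Mean and median differed in sign with NFAT5 against eGFP for macrophage markers, interferon response, calcineurin-NFAT genes, the unfolded protein response and the mitochondrial genome. With CA-RIT NFAT1 against eGFP they did so for osmotic stress targets, activation and AP-1 genes, the unfolded protein response, dendritic cell markers and CD4 and regulatory T cell markers, and in the last comparison for cytotoxic genes, interferon response and cholesterol biosynthesis. The test pointed down against a positive median, relative to the other genes, for stem-like and apoptosis genes with NFAT5 against eGFP and for residency, interferon, apoptosis and macrophage genes with CA-RIT NFAT1 against eGFP.

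The log2 fold changes of NFAT5 and CA-RIT NFAT1 against eGFP correlated with r = 0.80 over 14473 genes in the 8 libraries (jackknife SE over libraries 0.17), from 0.67 to 0.91 with 1 library left out, with the same sign in 84.8%. Simulated groups with no effect against the same controls gave a median r of 0.63 (0.61 to 0.65 in 20 simulations) and the same sign in 70.7%. The covariance was 2.48 against 1.10 simulated. Over 10 libraries the values were r = 0.80 (jackknife SE 0.23), from 0.63 to 0.93 with 1 library left out, against 0.67 (0.64 to 0.68), the same sign in 78.2% against 71.4%, and covariance 2.37 against 1.44. The comparisons share their controls, which were too few to be split, so a likeness of the vectors' effects is not shown.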

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

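The explanations below were chosen only after the patterns had been seen, so each test weighs a pattern that was already known. Of 83 values checked for a library far from the others in the group of 4 CA-RIT NFAT1 libraries, 19 had such a library by Dixon's test at 95% confidence. CA-RIT NFAT1 10 was that library for 18 of them. Chance alone would pick about 1 in 20 of unrelated values. These values are related, and some genes among them were named from fits that hold CA-RIT NFAT1 10, so that rate is no standard for the count. Its median correlation with the 7 reference libraries was 0.625, against 0.954 to 0.963 for the others of its group. Cd8a was at 0.0308 CPM (582 to 629 in the others) and Serpinb9b at 0 (128 to 151). Genes higher there were Arhgap21 at 52.3 CPM (17.6 to 23.0), Fam198b at 102 (2.73 to 6.14), Gpt2 at 76.7 (2.48 to 8.89), H2-Ab1 at 1139 (45.5 to 67.0), Jade3 at 21.5 (6.19 to 8.15), Nhlrc1 at 53.4 (0.471 to 0.993), Plbd1 at 117 (0.976 to 1.99), Ptpn6 at 659 (219 to 284) and Socs1 at 61.4 (18.3 to 22.6). Of 6 list scores, exhaustion transcription factors were at 3.84 (6.26 to 6.49), cytotoxic effector genes at 2.86 (6.25 to 6.61), T cell activation and AP-1 genes at 4.02 (5.79 to 6.08), the T cell receptor complex at 3.80 (8.57 to 9.05), NK and B cell markers at 0.170 (1.43 to 1.61) and mast cell and P511 markers at 4.08 (1.40 to 1.85). Fgf9 was at 0.0337 CPM in CA-RIT NFAT1 2 and 0 in the others.

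CA-RIT NFAT1 10 lacked T cell transcripts. RNA of other cell types fits: it was the highest of 10 libraries for 39 of 41 markers seen, 14 of 14 of mast cells and P511 and 25 of 27 of macrophages. Markers seen were those at 5 CPM or more in any library, this one included. A marker that passed only through it counts as highest there by construction, so these counts overstate the fit. The mast cell and P511 list score, which has no such filter, was 4.08 there against 1.40 to 1.85 in the others of its group. Low depth was excluded, with 32.5 M reads against a median of 28.3 M in 9 libraries. An effect of the vector was excluded as the cause, because the lowest T cell receptor score of the other CA-RIT NFAT1 libraries was 8.57, close to the lowest with NFAT5 (8.62). Xist, a gene expressed in female cells, had 0 reads there and lay between 3.51 and 11.4 CPM in the 8 libraries. Ddx3y, a gene of the Y chromosome, had 0 reads in all 10. Which cells gave the macrophage transcripts, and how the RNA of other cells came to make up this library, was not tested.

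eGFP control 3 lacked moderately expressed genes. Low depth was excluded, with 36.6 M reads, the most of any library. Few RNA molecules at the start of library making fits: of genes at 5 to 10 CPM 18.9% had 0 reads, and 10.2%, 3.40% and 0.0765% at 10 to 20, 20 to 50 and above 50 CPM. Transcript length fits too, since at 5 to 10 CPM the share at 0 was 4.23 times as high in the longest genes (28.4%) as in the shortest (6.70%). Zeros that gather among genes at low levels can arise in other ways too, so the first of these tests does not favour few molecules over another cause. Both stay open, and no biological explanation was tested.

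Inhibitory receptors were lower with NFAT5 than with eGFP over 8 libraries. A trend with transcript length was excluded as the whole cause, since the median was -1.01 with it removed. Dependence on a single control library could not be decided. The fits without eGFP control 3 or 6 each left a single control, assumed to vary like the other groups. The higher adjusted p of these fits by camera at the preset correlation, 0.0284, therefore excludes nothing. The list median stayed between -1.24 and -0.68 with 1 library left out, so only its direction held without either control. Members moving together between libraries of a group fits its prediction, with adjusted p = 0.931 by camera with an estimated correlation. That test cannot single out this list, because it passed none of the 84 pairs over 8 libraries (lowest adjusted p = 0.931). Its power to find a real shift was not measured. The call may still rest on a few libraries rather than on NFAT5. The biological reading, an effect of NFAT5 on these genes, was neither excluded nor shown.

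The groupings of libraries were also compared with all other splits of the same libraries. The real count of genes was 0 in each comparison, and every split must equal or exceed that. The shares of splits with as many genes therefore decide nothing. For NFAT5 against eGFP, 10 splits are too few for a share below 0.05: the count of genes was 0 in the real split and at most 0 in the others (10 of 10 as large), and 7 lists were called against at most 7 (2 of 10 as large). For CA-RIT NFAT1 against eGFP, 35 of 35 splits gave as many genes as the real 0, and a split with CA-RIT NFAT1 2, 4 and 9 and eGFP control 6 on the same side called 1345, the most of any split. On its other side were eGFP control 3 and 7 and CA-RIT NFAT1 10, the 3 libraries with median correlations of 0.837, 0.234 and 0.625 with the reference libraries. That points to a structure of the samples other than the groups, which parts these 3 libraries from the rest of the 2 groups. For lists there, 22 of 35 splits gave as many as the real 9, with up to 14. For CA-RIT NFAT1 against NFAT5, 35 of 35 splits gave as many genes as the real 0 (at most 0), and 31 of 35 gave as many lists as the real 7 (at most 15). Over 8 libraries the 10 splits of that comparison are again too few, with 0 genes against at most 0 (10 of 10 as large) and 4 lists against at most 11 (7 of 10 as large). These numbers of lists do not set the groups apart from other splits.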

How the results depend on the processing

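The fits with 8, 7 and 6 libraries, the removal of the length trend and the other scalings for 8 libraries were chosen after seeing the data. With 1 library left out, single results kept direction and side of the threshold in 1068 cases, were reversed in 59, stronger in 38 and weaker in 17. Under other settings they kept both in 944 cases, were reversed in 46, stronger in 32 and weaker in 39. The cause was not tested for any value below, except that eGFP control 7 alone held high levels of Nphs1, Shank1, Snx22 and Fgf9. Nfat5 in NFAT5 against eGFP stayed between 3.40 and 5.83 with 1 library left out. Upper-quartile scaling gave no value for 10 libraries, because the upper quartile of eGFP control 7 is 0 reads. No paired analysis was possible because the titles carry running numbers and no number is shared between groups. Depth limits every comparison with eGFP control 7, and thinning to its depth left 1347 genes.

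Counts of genes changed were 0 in edgeR in each comparison over 10 and over 8 libraries. Over 10 libraries DESeq2 gave 10 for NFAT5 against eGFP, 13 for CA-RIT NFAT1 against eGFP and 1 for CA-RIT NFAT1 against NFAT5, and voom gave 1, 2 and 0. Over 8 libraries DESeq2 gave 104, 60 and 1, and removal of the length trend gave 1 for CA-RIT NFAT1 against eGFP. With 1 library left out the counts ran from 0 to 506 and from 0 to 639 over 10 libraries and from 0 to 3294 and from 0 to 3410 over 8, for NFAT5 and CA-RIT NFAT1 against eGFP. Where a control alone was left, it was assumed to vary like the other groups. The 23 list calls over 10 libraries ran from 7 to 25 with 1 library left out, and were 0 with an estimated correlation. Fry, which asks a different question, passed 0 lists for a move in 1 direction. The 16 over 8 libraries were 0 with either as well.

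In NFAT5 against eGFP, log2 fold changes were reversed for Shank1 over 7 libraries (1.31) and for Nphs1 in voom (0.41), over 8 libraries (0.83) and over 7 (1.06). With 1 library left out, Pdcd1 ran from -1.30 to 0.0459, Lag3 from -1.34 to 0.77, Tox from -0.58 to 0.32, Ifng from -0.95 to 0.27 and Nphs1 from -12.82 to 0.84. Over 8 libraries Lag3 ran from -1.45 to 0.70, Tox from -0.63 to 0.34 and the mitochondrial respiratory chain list from -0.70 to 0.17.

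In CA-RIT NFAT1 against eGFP, DESeq2 reversed Nfat5 (-0.23), Lag3 (0.13) and Tox (0.0477), and voom reversed Nfat5 (-0.0325), Gzmb (0.29) and Shank1 (0.57). Tox was also reversed with RLE (0.0381), only the compared groups (0.0049) and the length offset (0.0803). Over 8 libraries Lag3 (0.23), Tox (0.28), Nphs1 (0.46), Snx22 (0.13), Shank1 (0.15) and Fgf9 (1.74) were reversed, and over 7 Nfat5 (-0.22), Nphs1 (0.70), Shank1 (2.41) and Fgf9 (1.70). With 1 library left out, Nfat5 ran from -0.64 to 1.83, Pdcd1 from -0.56 to 0.24, Lag3 from -1.04 to 1.17, Tox from -0.69 to 0.39, Nphs1 from -13.32 to 0.33, Shank1 from -11.91 to 0.16 and Fgf9 from -17.04 to 1.47. Over 8 libraries Tox was reversed in voom (-0.0405) and with the length trend removed (-0.31). With 1 of the 8 left out, Nfat5 ran from -0.22 to 2.26, Pdcd1 from -0.56 to 0.0128, Lag3 from -0.58 to 1.51 and Tox from -0.29 to 0.76.

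In CA-RIT NFAT1 against NFAT5, Nfatc2 was reversed with the length offset (0.10), in voom (0.35) and over 8, 7 and 6 libraries (0.27, 0.27 and 0.27). Over 8, 7 and 6 libraries Tcf7 (0.34, 0.34 and 0.34), Ifng (0.0335, 0.0318 and 0.0313) and Gzmb (0.24, 0.24 and 0.24) were reversed too. Gzmb was also reversed in DESeq2 (0.0511), with RLE (0.0511) and in voom (0.40), and Pdcd1 (-0.27) and Havcr2 (-0.0759) with thinned counts. With 1 library left out, Nfatc2 ran from -0.60 to 0.28, Pdcd1 from -0.15 to 1.16, Havcr2 from -0.0022 to 0.75, Lag3 from -0.59 to 1.30, Tox from -0.61 to 0.59, Tcf7 from -0.42 to 0.34, Ifng from -0.60 to 0.0440 and Gzmb from -0.32 to 0.27. Over 8 libraries Ifng was reversed in voom (-0.12) and the dendritic cell markers list with a mean CPM of 5 (-0.0524). With 1 of the 8 left out, Nfatc2 ran from -0.0690 to 0.60, Lag3 from -0.0106 to 1.71, Tox from -0.16 to 0.94 and Ifng from -0.13 to 0.16. The correlation of effects stayed between 0.63 and 0.93 over 10 libraries and between 0.67 and 0.91 over 8.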

Other observations

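The relations below were looked at only after the list results had been seen. Over the 8 libraries, the score of inhibitory receptors correlated with that of glycolysis and hypoxia (r = 0.88, exact permutation p = 0.00556, adjusted p = 0.143 over 28 relations), of cytokines (r = 0.81, adjusted p = 0.143) and of cell cycle (r = -0.79, adjusted p = 0.143). None of the 28 relations passed an adjusted p of 0.05. Without the 2 farthest libraries these were 0.86, 0.73 and -0.86.

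Hspa1a, a heat shock gene, was at 1635 CPM in NFAT5 1, 2820 in CA-RIT NFAT1 2 and 3625 in eGFP control 6, against 245 in eGFP control 3 and 301 in NFAT5 8. Miga1 was at 102 and 141 CPM in eGFP control 3 and 6, between 17.6 and 29.6 in the 6 libraries with NFAT5 or CA-RIT NFAT1 among the 8, and at 87.3 in CA-RIT NFAT1 10. For 8634 moderately expressed genes, the log2 level in a library was taken relative to the gene's mean over the 8 libraries. The Spearman correlation of these differences with transcript length was 0.65, -0.01 and -0.24 in NFAT5 1, 5 and 8, 0.49, 0.50 and -0.10 in CA-RIT NFAT1 2, 4 and 9, and -0.53 and 0.22 in eGFP control 3 and 6.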
